A study of Solanum lycopersicum with 8 samples.

How the data were processed

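Per the labels, RNA came from tomato pericarp kept in RNAlater, was labelled with Cy3 by the Quick-Amp method and was hybridised to one-colour Agilent arrays. There were 8 arrays, 1 for each of 2 genotypes, wild type and the ur mutant, at each of 4 stages. The intensity values in the deposited scanner files were, per the file headers, spot brightness corrected within each array for background and spatial trend, and not normalized between arrays. The submitters' processing notes name Agilent Feature Extraction 11.5.1.1. The log2 values in the deposited series table have no stated method. Set against the scanner files at gene names with 1 spot, they had a slope of 1 on the log2 signal, the same direction. They had a 75th percentile near 0 on each array and 1 value per gene name, by a rule for several probes that was not checked. Their array medians were -3.096, -3.257, -3.301 and -3.369 in wild type and -3.032, -3.164, -3.037 and -3.129 in ur, in stage order.

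Each array held 62976 spots, of which 1319 were controls. The files of the 4 ur arrays had been saved again with 3 or fewer significant digits, and gave the gene name in place of the probe name on 61657 spots. They were therefore joined to the wild type files by feature number. The median signal over the local background was 9.47, 7.20, 5.63 and 5.31 in wild type and 8.14, 4.42, 6.77 and 5.50 in ur, no spot was saturated, and between 281 and 343 spots per array carried an outlier flag. The 2 slides, read from the file names, each held 1 genotype.

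Log2 processed signals were averaged over the spots of a probe, after control and outlier-flagged spots were left out, and the 75th percentile of each array was subtracted. Probes well above background on at least 2 arrays were tested, 37421 in number, for 29281 gene names. Of these names 4021 had an informative description, not one of an unknown or hypothetical product, a clone or a bare sequence record. Among the tested probes were 128 antisense probes. A further 78 probes were left out because all their spots were flagged on an array. A straight line over the 4 stages was fitted for each genotype with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend. The contrasts were the wild type slope, the ur slope, their difference, and ur minus wild type at the mean stage, each at a Benjamini-Hochberg adjusted p of 0.05. Log2 differences and slopes use the measured signal also on arrays where a probe was dim, meaning not well above background. A fold between genotypes or arrays whose lower side was dim is given as a lower bound, with the background in place of the dim signal. Data were read with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15 and with the R package data.table, version 1.17.8, and drawn with matplotlib 3.10.9.

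Gene lists were tested with camera at a correlation of 0.01 between genes, adjusted over the lists within each contrast, and again with an estimated correlation. The lists were ripening regulators, ethylene synthesis, ethylene perception and response, carotenoid synthesis toward lycopene, carotenoid cyclization, cell wall softening, flavour volatiles, flavonoids, chlorophyll breakdown, sugar and acid metabolism, cuticle, reference genes, photosynthesis, seed markers, heat shock, pathogenesis-related, cell division and the cytosolic ribosome. The probe with the highest mean signal stood for a gene, which may be a probe of the cross-hybridising type, and a list needed 3 measured genes. Single arrays were compared without a test, by counts of probes at least 4-fold apart and by list medians set against 10000 random lists matched in 20 bins of mean signal.

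The tests, the lists and the rule for naming genes were chosen before the data were examined. The rule named a fixed set of ripening genes and up to 3 further members of each list with the largest values. It also named the 5 highest and 5 lowest values of each contrast among the 4021 gene names with an informative description, so other gene names were not ranked. Where fewer passed the threshold, the largest by size were named from probes well above background on all arrays. Further members named in the report as examples, among them FUL1, GGPS2, PDS, DXS1 and CHS2, come from the table this rule filled.

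Genes were matched by accession, symbol or description. Of 1119 RefSeq accessions on the array 1052 were found in the reference names, which rest on the assembly SLM_r2.1 and were used for nothing else. One gene may have several array names. E4 and E8 were matched by description only. The accessions listed for E8, CHI and GAPDH were left out because their chromosome there is not that of the listed locus. No entry was matched for CNR, NOR-like1, DML2, Z-ISO, CRTISO, PL, F3'H, FLS, PPH, ALMT9, CD1, CER6, CYP86A69, SHN3, CAC, TIP41, EXPRESSED, actin or UBI3. The array description of the ACO3 entry gives another name.

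The alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, the deposited value table, no filter on dim probes, a filter asking for all 8 arrays, early against late stages, no mean-variance trend, stage as a block, a 2-fold rule, an estimated correlation, the mean over all probes of a gene, and each array left out in turn. Scaling on 8 spike-in probes, mature green against the 3 later stages, and the nuclear-encoded photosynthesis genes alone were added after the data were seen. Chloroplast-encoded entries were recognised by name or description. The fits were tested on simulated data with 100 probes changed by 1 log2 unit per stage and 100 by 2 in each slope, and as many by 1 and 2 log2 units in the mean difference. The wild type slope recovered 28 and 72 of them, the ur slope 31 and 61, and the mean difference 1 and 22. The slope difference recovered 11 and 86 of 200. False calls were 4 of 104, 7 of 99, 0 of 23 and 4 of 101 in that order. The simulated errors were independent between arrays, with no slide effect and no curved course, so these shares may not hold for the real arrays.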

Results

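Transcript levels were measured in the pericarp, the fruit wall, of tomato (Solanum lycopersicum) from wild type plants and from a mutant line, Unripening Mutant 2 in the labels and ur here. Fruit of each genotype was taken at 4 stages, mature green, breaker, turning and ripening, with 1 one-colour array per genotype and stage and so no replicate of any stage. Each array carried 50200 probes for 40387 gene names, and 37421 probes were tested. Between 65.7% and 71.9% of the spots on the wild type arrays and between 63.8% and 70.3% on the mutant arrays were well above background. The median signal was 4.42 to 9.47 times the local background, and the number of arrays limits the precision of every value. Levels are log2 signals minus the 75th percentile of the same array. The 4 stages of a genotype are not replicates, so the p-values of the stage trends and of the mean difference measure spread about 2 straight lines, with 4 residual degrees of freedom. The labels do not name the gene changed in ur, so no targeted gene could be used to check them.

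The trend over stages in wild type fruit was read from 1 array per stage. Genes of carotenoid synthesis toward lycopene, the red pigment, rose as a group in camera, as did genes of ethylene perception and response and of flavour volatiles, but not with an estimated correlation (adjusted p = 0.463, 0.564 and 0.564). Genes of photosynthesis, pathogenesis-related genes and cell division genes fell as groups, again not with an estimated correlation (adjusted p = 0.586, 0.528 and 0.463). AGPS1 and AGPL1, the subunits of the enzyme that opens starch synthesis, fell by 1.82 and 2.17 log2 units per stage (limma adjusted p = 0.0408 and 0.0424), although AGPL1 was well above background on only 2 wild type arrays. In limma, 226 probes of 195 gene names passed an adjusted p of 0.05, 23 rising and 203 falling, and 7292 had an unadjusted p under 0.05. The count was 0 without any 1 of the 4 wild type arrays, without the mutant mature green array or without the mutant ripening array, 73 without mutant breaker and 419 without mutant turning. It was also 0 after quantile normalization, from the deposited value table and without the mean-variance trend.

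All 6 measured lycopene genes had slopes above 0 in wild type, with a median of 0.64 log2 units per stage (camera adjusted p = 5e-04, and adjusted p = 0.463 with an estimated correlation). None of the 6 passed over all probes, while 5 passed when adjusted over the list alone. Phytoene synthase PSY1, the first committed enzyme of the pathway, stood at 3.52 on the mature green array and 6.62 on the ripening array, ZDS at 1.67 and 3.46, and PDS at 0.90 and 2.84. Of 14 ethylene perception and response genes, 11 had slopes above 0, with a median of 0.28 (camera adjusted p = 0.0424, and adjusted p = 0.564 with an estimated correlation), and 1 passed when adjusted over the list alone. The receptor NR went from 0.57 to 3.74, and the ripening-related genes E4 and E8 from 4.64 to 6.33 and from -5.75 to -2.02, none past the threshold. All 5 flavour volatile genes had slopes above 0, with a median of 0.60 (camera adjusted p = 0.0424, and adjusted p = 0.564 with an estimated correlation), among them the alcohol acyltransferase AAT1, at 1.35 and 5.86, and the lipoxygenase LOXC, at -3.05 and 1.49, with none past the threshold even when adjusted over the list alone. Without the wild type mature green array the camera adjusted p was 0.599 for the ethylene list and 0.599 for the volatile list, with medians of 0.01 and 0.22. The ethylene list was also lost without wild type ripening (0.0693) or mutant ripening (0.0521), and the volatile list without wild type turning (0.0642, median 0.61). With all arrays kept, the ethylene list was lost with normexp (0.201), quantile normalization (0.0745), median centring (0.0655), no filter (0.0941), the filter on all 8 arrays (0.111), early against late stages (0.117) and the mean over all probes (0.0524), and the volatile list with normexp (0.0544), quantile normalization (0.107), median centring (0.0797), no filter (0.0848) and the filter on all 8 arrays (0.111). Early against late stages aside, the medians in these settings were 0.201 to 0.382 for ethylene and 0.442 to 0.699 for volatiles.

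Of 62 photosynthesis genes, 40 had slopes below 0 in wild type, and the list fell with a median of -0.10 (camera adjusted p = 0.000432, and adjusted p = 0.586 with an estimated correlation). Split by genome after the values were seen, its 31 nuclear-encoded genes had a median of -1.13 and its 31 chloroplast-encoded genes 0.00 after rounding. In this list 4 genes passed over all probes, all falling, and 15 passed when adjusted over the list alone. The light-harvesting entries TA36068_4081, TA36417_4081 and TA36418_4081 fell by 2.62, 1.73 and 1.57 per stage (limma adjusted p = 0.0439, 0.0408 and 0.0408). Without the wild type ripening array the list median was 0.10 (camera adjusted p = 0.653), and for mature green against the 3 later stages it was 0.03 (camera adjusted p = 0.859). Pathogenesis-related genes had 24 of 28 slopes below 0, a median of -1.06 (camera adjusted p = 3.62e-07, and adjusted p = 0.528 with an estimated correlation) and no gene past the threshold over all probes, while 2 rising and 11 falling genes passed when adjusted over the list alone. The pathogenesis-related entry NM_001247594 was at least 111-fold lower on the ripening array than at mature green, and the proteinase inhibitor NM_001247686 went the other way, from -1.38 to 4.09. Cell division genes had 29 of 43 slopes below 0, a median of -0.24 (camera adjusted p = 0.00463, and adjusted p = 0.463 with an estimated correlation), no member past the threshold over all probes and 5 when adjusted over the list alone. A histone H4 entry, NM_001247192, stood at 3.50 at mature green and -3.64 at ripening. Without the wild type ripening array the cell division list had a camera adjusted p of 0.258, and for mature green against the later stages 0.0605.

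Outside the lists, among genes with an informative description, the lowest wild type slopes past the threshold were those of the subtilisin-like protease P69B (-3.28, limma adjusted p = 0.0455), an EIX receptor entry, TA56617_4081 (-2.90, limma adjusted p = 0.0444), a CLE peptide entry, TA40353_4081 (-2.87, limma adjusted p = 0.0408), and an amino acid permease entry, TA53781_4081 (-2.57, limma adjusted p = 0.0484). Each of these 4 was well above background on 3 of the 4 wild type arrays, so its slope rests partly on a dim signal. Among the named genes the largest upward slopes were those of MAN4 and polygalacturonase entries, and none of these passed. Polygalacturonase PG2a, which digests pectin, stood at -3.02 at mature green, 6.43 at breaker, 6.70 at turning and 6.69 at ripening (slope 2.94, limma adjusted p = 0.221). The mannanase MAN4 was not well above background at mature green and was at least 2890-fold higher on the ripening array. The slope of MAN4 was 3.61 (limma adjusted p = 0.262). The cell wall list had 7 of 9 slopes above 0, a median of 0.61 (camera adjusted p = 0.16), no member past the threshold and 1 rising and 1 falling member when adjusted over the list alone.

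The same fit gave the trend over the 4 stages in ur fruit. Its count of calls is no test of a difference from wild type. The ur trend takes the stage labels of the ur arrays as given, and an exchange of stages among them stays open, as set out under the flagged results. No probe passed in limma, 4096 had an unadjusted p under 0.05 (2086 with slopes above 0 and 2010 below), and the smallest adjusted p was 0.186. Without the mutant turning array 77 probes passed. Cytosolic ribosome genes fell as a group, with 47 of 54 slopes below 0 and a median of -0.15 (camera adjusted p = 5.85e-06, and adjusted p = 0.646 with an estimated correlation). Pathogenesis-related genes fell as well, with 22 of 28 slopes below 0 and a median of -0.58 (camera adjusted p = 7.32e-05, and adjusted p = 0.646 with an estimated correlation). Adjusted over the list alone, no ribosome gene passed, while 1 rising and 7 falling pathogenesis-related genes did. The ribosome list was lost without the mutant mature green array (camera adjusted p = 0.453), and the pathogenesis-related list without the mutant ripening array (0.581), with the filter on all 8 arrays (0.136) and for early against late stages (0.0526).

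By size, among genes with an informative description, the lowest ur slopes were those of non-specific lipid transfer proteins and pectin methylesterase. The lipid transfer protein LE16 stood at 5.05, 4.49, 4.80 and -4.99 on the 4 ur arrays in stage order, ltpg1 at 5.25, 4.78, 4.72 and -4.81, and the entry TA36388_4081 at 6.15, 6.54, 5.94 and -4.37. The pectin methylesterase PME2.1 stood at 4.50, 3.54, 2.05 and -4.64. The highest slopes were those of a CBF3 transcription factor entry, DV103683, from -2.42 to 4.54, the protease inhibited by a Phytophthora protein, pip1, from -0.69 to 5.08, INT9 (JX100461) from -2.94 to 3.31, and the plastid tRNA-Ala gene LyesCt027 from -1.16 to 4.54. The cell wall list had a median of -0.91 (camera adjusted p = 0.143), with 2 falling members adjusted over the list alone, and the lycopene list a median of 0.19 (camera adjusted p = 0.192). The flavonoid list had a median of -1.03 (camera adjusted p = 0.191), and without the mutant ripening array its direction turned to up (camera adjusted p = 0.000801), while without mutant mature green or mutant turning it passed downward (0.000299 and 0.0265). In the photosynthesis list the median was 0.16 and the mean -0.15 (camera adjusted p = 0.825), with 6 falling members adjusted over the list alone, and without the mutant mature green array the list fell (camera adjusted p = 1.16e-05), while without mutant ripening it rose (9.4e-06). Split by genome, its nuclear-encoded genes had a median of -0.472 and its chloroplast-encoded genes 0.285, so the list pools opposite courses.

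**Figure D1:**
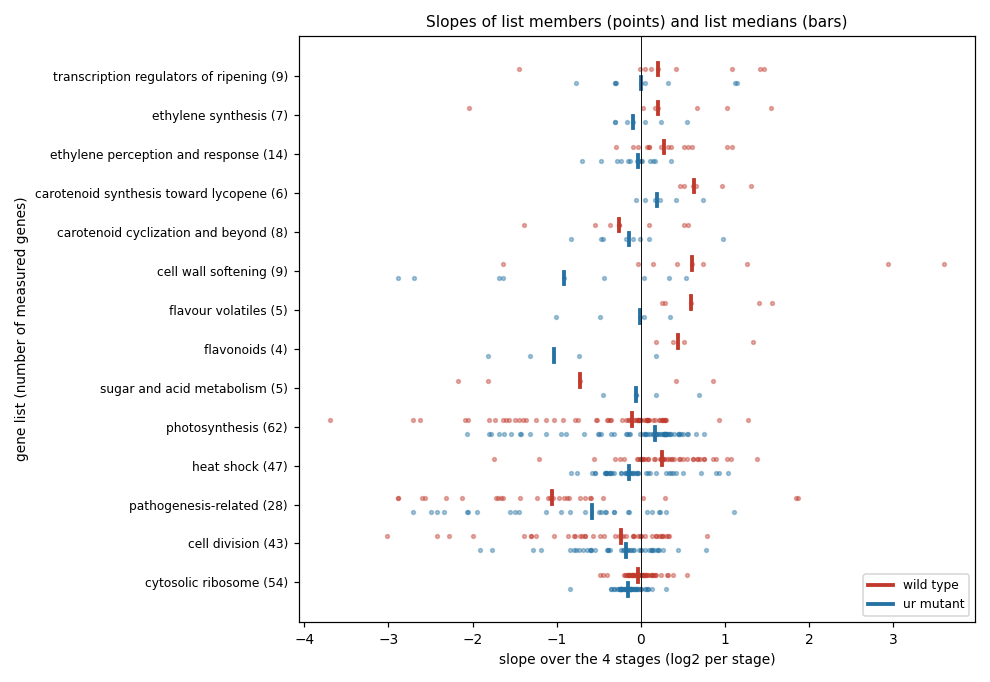
Slopes over the 4 stages, in log2 units per stage, of the members of each tested gene list in wild type (red) and ur (blue). Points are genes and bars are list medians. The lycopene list has a median of 0.64 in wild type and 0.19 in ur, and the cell wall list 0.61 and -0.91.

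The difference of the 2 trends asked which genes took another course in ur than in wild type. In camera 7 gene groups did by the labelled stages, and none with an estimated correlation (adjusted p = 0.474 to 0.576). The comparison depends on the labelled order of the ur arrays. Over the 226 probes of the wild type trend, ur slopes in that order correlated with wild type slopes at 0.268, and in the best other order at 0.579. Lists that lay lower in slope in ur were ethylene perception and response, carotenoid synthesis toward lycopene, cell wall softening, flavour volatiles, heat shock and the cytosolic ribosome, and photosynthesis lay higher. Single genes did not pass: limma called 0 probes, 3681 had an unadjusted p under 0.05 (2224 with a higher slope in ur and 1457 with a lower one), and the smallest adjusted p was 0.093. A shift common to all arrays of a genotype cancels in this comparison.

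The cell wall list had 7 of 9 slope differences below 0, a median of -1.22 (camera adjusted p = 0.0115, and adjusted p = 0.474 with an estimated correlation) and 1 member with a lower slope in ur adjusted over the list alone. PG2a reached 5.22 at breaker in ur and stood at -2.14 at ripening, a slope difference of -4.58, and MAN4 had a slope difference of -5.29. The 5 volatile genes all had slope differences below 0, with a median of -1.06 (camera adjusted p = 0.0115, and adjusted p = 0.474 with an estimated correlation). The lipoxygenase LOXB had a slope of 0.60 in wild type and -1.01 in ur. In the lycopene list 5 of 6 differences were below 0, with a median of -0.52 (camera adjusted p = 0.021, and adjusted p = 0.474 with an estimated correlation), GGPS2 having the lowest at -1.26. In the ethylene perception and response list 11 of 14 were below 0, with a median of -0.44 (camera adjusted p = 0.0117, and adjusted p = 0.474 with an estimated correlation), E8 having the lowest at -1.33, NR standing at -1.07 and E4 at -0.99. Heat shock genes had 38 of 47 differences below 0 and a median of -0.40 (camera adjusted p = 0.021, and adjusted p = 0.576 with an estimated correlation). Ribosome genes had 45 of 54 below 0 and a median of -0.11 (camera adjusted p = 0.0082, and adjusted p = 0.474 with an estimated correlation). From mature green to ripening the ribosome list had a median of -0.168 in wild type and -0.505 in ur. Random lists matched on mean signal had 0.26 and 0.006, so they also moved lower in ur than in wild type. Photosynthesis genes had 51 of 62 above 0 and a median of 0.31 (camera adjusted p = 0.000212, and adjusted p = 0.49 with an estimated correlation), and the chlorophyll-binding entry BG128483, dim on 1 wild type array, had a slope of -3.70 in wild type and -1.63 in ur. Adjusted over the list alone, 0 genes of the volatile, lycopene, ethylene response, heat shock, ribosome and photosynthesis lists passed.

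Several of these calls were lost without a single array or with other processing. Without the wild type mature green array the camera adjusted p was 0.278 for ethylene response, 0.451 for lycopene, 0.163 for cell wall, 0.189 for volatiles and 0.137 for heat shock, with medians of -0.04, -0.20, -1.18, -0.45 and -0.25, so that the cell wall median hardly moved. Without wild type ripening it was 0.785 for photosynthesis, 0.359 for heat shock and 0.0819 for the ribosome, with medians of 0.12, -0.46 and -0.07, the heat shock median being no smaller than before. Without mutant mature green it was 0.786 for the ribosome and 0.448 for photosynthesis, which turned direction. Without mutant ripening it was 0.107 for lycopene (median -0.46) and 0.164 for volatiles (median -0.33), and without mutant turning 0.0689 for heat shock (median -0.31). The number of lists past the threshold was 7 over all arrays, 2 without wild type mature green and 4 without wild type ripening. The heat shock call was lost with normexp (0.0667), quantile normalization (0.0769), median centring (0.0631), no filter (0.289) and the filter on all 8 arrays (0.0736). The medians there were -0.387, -0.338, -0.486, -0.346 and -0.405, so the difference stayed about as large. The heat shock call was also lost for mature green against the later stages (0.455). Quantile normalization also lost the lycopene (0.0696, median -0.422) and ribosome (0.426, median -0.0163) calls.

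By size, the highest slope differences among named genes included jasmonate genes. JAZ2, a repressor of jasmonate signalling, had a slope of -2.25 in wild type and 0.68 in ur, the JAZ1 entry TC217737 -2.09 and 0.60, and allene oxide synthase AOS -1.77 and 0.88. The starch gene AGPL1, dim on 2 wild type arrays, had a slope difference of 2.12 and AGPS1 of 1.38, and both passed when adjusted over the sugar and acid list alone. That list had a median slope difference of 1.38 (camera adjusted p = 0.0615). In the flavonoid and carotenoid cyclization lists 1 member each had a lower slope in ur when adjusted over the list alone. The 1 measured cuticle gene also had a lower slope, at an unadjusted limma p under 0.05.

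**Figure D2:**
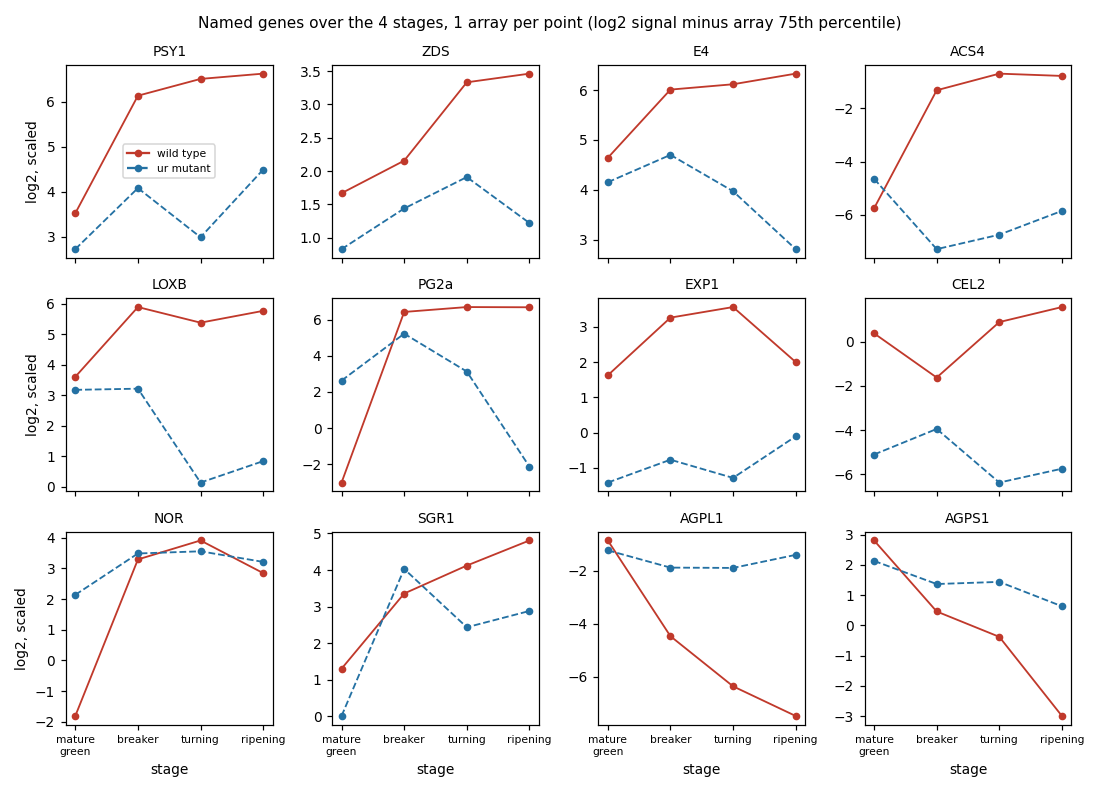
Scaled log2 levels of 12 named genes at the 4 stages, 1 array per point, in wild type (red, solid) and ur (blue, dashed). PG2a stands at 6.69 in wild type and -2.14 in ur at ripening, while PSY1 stands at 6.62 and 4.49.

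Of the 4 fitted contrasts, the mean difference between ur and wild type over the stages had the most probes past the threshold. Lycopene, cell wall, flavour volatile, flavonoid, heat shock and ribosome genes were lower in ur as groups in camera, but not with an estimated correlation (adjusted p = 0.658 for each). The cellulase CEL2 was at least 45.5-fold lower in ur, the expansin EXP1 11.4-fold, the lipoxygenase LOXB 9.97-fold and phytoene synthase PSY1 4.36-fold, while AGPL1 was at least 7.05-fold higher. In limma 3258 probes of 2730 gene names passed, 1802 higher and 1456 lower in ur, and 10420 had an unadjusted p under 0.05. All wild type arrays lay on 1 slide and all ur arrays on another, so batch and group cannot be told apart here or in any single-stage comparison of the genotypes. The count was 1463, 931, 732 and 967 without wild type mature green, breaker, turning and ripening, 383 without mutant mature green and 909 without mutant ripening. It was 1504 when arrays were scaled on spike-in spots, with 57% of the calls lower in ur in place of 44.7%, and 695 with stage as a block.

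In the lycopene list 5 of 6 genes were lower in ur, with a median of -1.17 (camera adjusted p = 0.00331, and adjusted p = 0.658 with an estimated correlation), 3 of them past the threshold over all probes and 5 when adjusted over the list alone. PSY1 was lower by -2.13, zeta-carotene desaturase ZDS by -1.30 and DXS1, which feeds the pathway, by -1.03 (limma adjusted p = 0.0453, 0.0314 and 0.0234). The DXS1 value rests on its brightest probe. It was 1.19 in the deposited value table (limma adjusted p = 0.522), which holds 1 value per gene name, and the call was kept in 6 of 13 alternatives. The cell wall list had 7 of 9 genes lower, a median of -1.99 (camera adjusted p = 0.0372, and adjusted p = 0.658 with an estimated correlation) and 2 genes past the threshold by both adjustments, CEL2, dim on 2 ur arrays, at -5.59 and EXP1 at -3.51 (limma adjusted p = 0.0102 and 0.0146). The volatile list had 4 of 5 genes lower, a median of -0.95 (camera adjusted p = 0.0321, and adjusted p = 0.658 with an estimated correlation), LOXB past the threshold at -3.32 (limma adjusted p = 0.0214) and 3 genes when adjusted over the list alone. LOXC, dim on 2 ur arrays, was at least 31-fold lower (limma adjusted p = 0.0507). All 4 flavonoid genes were lower, with a median of -3.30 (camera adjusted p = 0.0457, and adjusted p = 0.658 with an estimated correlation), none past the threshold and 1 when adjusted over the list alone. The cell wall call was lost without wild type breaker (camera adjusted p = 0.0566), mutant mature green (0.155) or mutant ripening (0.151), with medians of -0.86, -0.48 and -0.38, and the volatile call without mutant mature green (0.129) or mutant ripening (0.0507), with medians of -0.53 and -0.76. The flavonoid call was lost without wild type mature green (0.067), wild type breaker (0.0628), wild type ripening (0.0979), mutant mature green (0.232) or mutant ripening (0.281), with medians of -3.64, -3.03, -3.36, -1.23 and -1.19. By processing, the lycopene call was lost from the deposited value table (0.0632, median -1.11). The cell wall call was lost with quantile normalization (0.0768), median centring (0.0625), the value table (0.052) and the filter on all 8 arrays (0.121), with medians of -1.83, -2.09, -2.02 and -1.81. The volatile call was lost with that filter (0.121, median -0.942). The flavonoid call was lost with quantile normalization (0.0768), median centring (0.0654), no filter (0.236), the filter on all 8 arrays (0.179) and early against late stages (0.0568), with medians of -3.23, -3.4, -2.25, -3.58 and -3.3.

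Heat shock genes, which also respond to stress and handling, had 30 of 47 members lower in ur, a median of -0.79 (camera adjusted p = 0.000785, and adjusted p = 0.658 with an estimated correlation), 6 past the threshold and 13 when adjusted over the list alone. The entries FR828678 and FR828680 were lower by -1.82 and -3.61 (limma adjusted p = 0.0208 and 0.0407), and NM_001247562 by -1.66 (limma adjusted p = 0.0279). Ribosome genes had 44 of 54 members lower, a median of -0.17 (camera adjusted p = 0.00496, and adjusted p = 0.658 with an estimated correlation) and 1 past the threshold by both adjustments, a 60S ribosomal protein L15 entry, AI780188. That entry was not well above background on any ur array and was at least 585-fold lower (limma adjusted p = 5.53e-05). The ribosome call was lost without wild type mature green (camera adjusted p = 0.067) and with quantile normalization (0.346), where the median was -0.04. On single arrays in stage order the ribosome list stood at 0.05, -0.16, -0.24 and -0.32 in ur against wild type. Its percentiles among random lists matched on mean signal were 41.3, 0.23, 28.1 and 9.94. Those random lists had medians of 0.06, 0.06, -0.20 and -0.15, so part of the shift at turning and ripening was shared by other genes of like signal.

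In the other lists, the ethylene synthesis gene ACS4, above background on 1 ur array, was at least 10.6-fold lower (limma adjusted p = 0.0373), the ripening gene E4 lower by -1.87 (0.0227), and beta-carotene hydroxylase CRTRB2 by -1.58 (0.0109). AGPL1 and AGPS1 were higher (limma adjusted p = 0.0125 and 0.028), AGPS1 by 1.42, with a range of 0.38 to 1.62 over 13 alternatives and the call kept in 5 of them, and an endochitinase entry, BI209334, by 3.63 (0.0104). The chitinase CHI17 (NM_001247471), chosen after its values were seen, was lower by -1.83 (limma adjusted p = 0.0461). The light-harvesting entries TA36069_4081 and TA36418_4081 were lower by -1.45 and -1.46 (limma adjusted p = 0.0484 and 0.0289). The ethylene perception and response list had a median of 0.40 and a mean of -0.05 (camera adjusted p = 0.698), and the pathogenesis-related list a median of -0.26 and a mean of 0.01 (camera adjusted p = 0.698). Outside the lists, among genes with an informative description, the highest differences past the threshold were those of a CYP92B3-like cytochrome entry, TA43614_4081 (at least 8.66-fold), the polygalacturonase PGcat (at least 13.4-fold), the hydroxycinnamoyltransferase THT7-8 (at least 11.7-fold), a cellulose synthase-like entry, TA47070_4081, which was not well above background on any wild type array and was at least 9.1-fold higher in ur, and the subtilisin-like protease sbt3 (at least 14.7-fold). These 5 were dim on 3, 2, 2, 4 and 1 of the wild type arrays. Their limma adjusted p were 0.0432, 0.0147, 0.015, 0.023 and 0.0405. A histidine decarboxylase entry, TA36544_4081, was above background on 1 ur array and at least 314-fold lower (limma adjusted p = 0.0069).

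The named genes held 40 values past the threshold in the wild type slope and the mean difference together. Of these, 18, 15, 15 and 16 stayed past it without the wild type arrays in stage order, and 7, 28, 32 and 11 without the ur arrays in stage order. No wild type slope among them stayed past it under more than 4 of the 13 alternatives run, and the mean differences of TA53781_4081 did so under 3, of TA36069_4081 under 4, and of PSY1, ZDS, ACS4, AGPS1, JX100461, TA43614_4081 and sbt3 under 5. Those that passed under all 13 alternatives run for them were the L15 entry AI780188, the histidine decarboxylase entry TA36544_4081 and the MADS-box entries AF448522, DQ157795 and NM_001247908, the first 2 of them RIN.

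The ripening regulators as a list were not called between genotypes, with 6 of 9 genes higher in ur and a median of 0.20 (camera adjusted p = 0.773). In that list RIN is counted by the entry NM_001247741 alone, not by the RIN entries lost in ur. RIN and MC, which are MADS-box genes, stood out. RIN is known to switch on many ripening genes. The RIN array entries AF448522 and DQ157795 were well above background on all 4 wild type arrays and on no ur array, and were at least 717-fold and 650-fold lower in ur (limma adjusted p = 0.00108 for each). A MADS-box entry without a symbol in the reference table, NM_001247908, whose probe shares 17 bases with theirs, was above background on 1 ur array and was at least 1000-fold lower (limma adjusted p = 0.00146). The entry NM_001247741, named RIN in the reference table, stood at -0.16, 4.28, 2.51 and 4.25 on the ur arrays in stage order and between 1.202 and 5.69 on the wild type arrays, a mean difference of -1.65 (limma adjusted p = 0.27). The MC entry was higher in ur by 3.89 (limma adjusted p = 0.0291). It stood at 1.85, 0.62, -0.24 and -2.69 in wild type and at 0.86, 5.42, 3.66 and 5.19 in ur. Its probe has the same 60 bases as a probe of a RIN-MC entry, so its signal cannot be assigned to the MC gene alone. The probes of the RIN-MC entry were higher in ur by 3.86, 3.67 and 4.10 (limma adjusted p = 0.0307, 0.0342 and 0.0321). Without single arrays the MC call was lost for each wild type array and for mutant ripening, while AF448522, DQ157795 and NM_001247908 kept theirs.

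**Figure D3:**
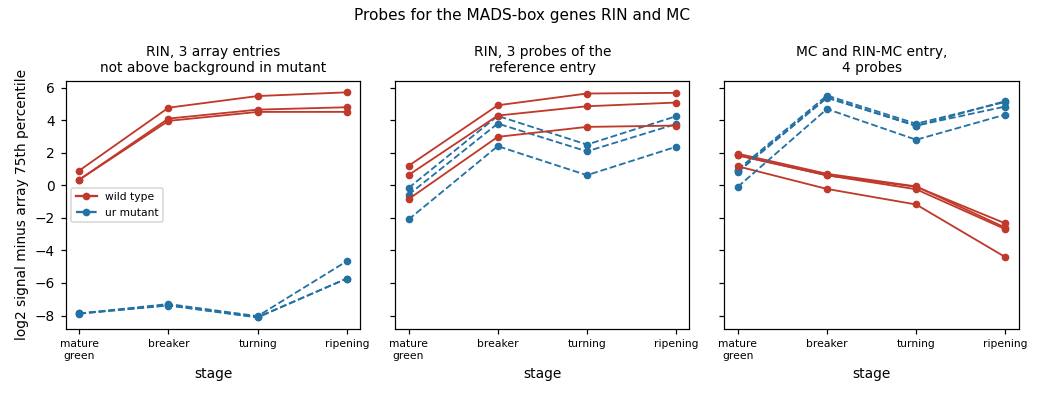
Scaled log2 levels at the 4 stages, 1 array per point, of the probes lost in ur (left), 3 probes of the RIN entry NM_001247741 (middle) and 4 probes for MC and a RIN-MC entry (right), in wild type (red, solid) and ur (blue, dashed). The left-hand probes of ur lie between -8.12 and -4.66. The MC probe has the same sequence as a probe of the RIN-MC entry.

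Among the other regulators, the NAC gene NOR stood at -1.81 at mature green and 3.29 at breaker in wild type and at 2.14 and 3.49 in ur, and FUL1 at 4.91 and 5.76 in wild type and 4.61 and 5.63 in ur. TAGL1 had a mean difference of 0.19 (limma adjusted p = 0.665). The regulator list had median slopes of 0.21 in wild type and 0.01 in ur (camera adjusted p = 0.173 and 0.85) and a median slope difference of -0.42 (camera adjusted p = 0.127). Ethylene synthesis had medians of 0.21 and -0.09 (camera adjusted p = 0.286 and 0.682), a median slope difference of -0.48 (camera adjusted p = 0.159) and a median mean difference of -0.62 (camera adjusted p = 0.211). Its members ACS2 and ACO1 had mean differences of -2.21 and -0.18 (limma adjusted p = 0.144 and 0.526). Carotenoid cyclization had medians of -0.26 and -0.13 (camera adjusted p = 0.553 and 0.474), a median slope difference of -0.10 beside a mean of 0.09 (camera adjusted p = 0.792) and a median mean difference of 0.10 (camera adjusted p = 0.938). In that list CYCB stood at -5.60 in wild type and -0.92 in ur at ripening, and LCYE went from -3.47 to not well above background in wild type. The sugar and acid list had medians of -0.73 and -0.05 (camera adjusted p = 0.122 and 0.825) and a median mean difference of 1.42 (camera adjusted p = 0.698).

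Cell division genes had a median mean difference of 0.00 after rounding, 21 of 43 being higher in ur (camera adjusted p = 0.938), a median slope difference of 0.04 (camera adjusted p = 0.159) and a median ur slope of -0.17 (camera adjusted p = 0.0926). Heat shock genes had median slopes of 0.26 in wild type and -0.14 in ur (camera adjusted p = 0.0958 and 0.37), and ribosome genes -0.03 in wild type (camera adjusted p = 0.536). The ur slope of ethylene response had a median of -0.03 (camera adjusted p = 0.474) and that of volatiles a median of 0.00 after rounding (camera adjusted p = 0.473). The flavonoid list had a median slope of 0.45 in wild type (camera adjusted p = 0.416) and a slope difference of -1.63 (camera adjusted p = 0.0654), the pathogenesis-related list a slope difference of 0.43 (camera adjusted p = 0.0871) and photosynthesis a mean difference of 0.27 (camera adjusted p = 0.752). Lists with fewer than 3 measured genes were not tested. Of the 2 chlorophyll breakdown genes, SGR1, which starts chlorophyll loss, went from 1.30 to 4.81 in wild type and from 0.01 to 2.88 in ur, and the red chlorophyll catabolite reductase entry AM233528 had a mean difference of 0.07. The cuticle gene CD2 had a mean difference of -0.32, and the reference gene EF1a one of -0.02. The 2 seed markers went in opposite directions, a late embryogenesis abundant entry with a mean difference of -1.94 and an oleosin entry with 1.24.

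Several of these list values passed when 1 array was left out, so a list not called here was not shown to be flat. Without mutant mature green the ur slope of volatiles had a median of -0.98 (camera adjusted p = 0.00775), of heat shock -0.51 (0.000569) and of cell wall -0.90 (0.0155). Without that array the slope difference of flavonoids was -3.59 (0.000821), of the regulators -1.33 (0.0334) and of sugar and acid genes 1.46 (0.0334), the mean difference of photosynthesis was 0.56 (0.00466), and the wild type slope of heat shock passed at 0.26 (0.0405), as it did without mutant breaker (0.00357). Without mutant ripening the mean difference of photosynthesis was 0.57 (0.0265), the slope difference of pathogenesis-related genes 0.91 (7.8e-05), and the ur slopes of heat shock and of sugar and acid genes passed at -0.13 (0.0239) and -0.35 (0.0191). Without mutant turning the flavonoid slope difference was -2.04 (0.00811). The pathogenesis-related slope difference also passed without wild type breaker (0.007) or turning (0.0431), the sugar and acid one without either as well (0.038 and 0.0431), and the ur slope of cell division without mutant breaker (0.0351) or turning (0.0406). With all arrays kept, normexp and median centring also called the pathogenesis-related slope difference (0.0224 and 0.0272), normexp the ur slope of cell division (0.0427), quantile normalization the wild type slope of the ribosome (0.0178), median centring and no filter the sugar and acid slope difference (0.0272 and 0.0397), and early against late stages the ur slope of heat shock (6.96e-06). Of the alternatives added after the data were seen, spike-in scaling called the wild type slopes of cell wall and heat shock (0.00609 and 0.00153), the ur slopes of cell wall and cell division (0.0337 each) and the slope differences of flavonoids and of sugar and acid genes (0.00683 and 0.0237). Mature green against the later stages called the wild type trend of the regulators (0.0167), the ur trends of lycopene and photosynthesis, both upward (0.00935 and 4.31e-08), and the trend differences of the regulators, ethylene synthesis and pathogenesis-related genes (0.0426, 0.00773 and 0.00342). None of these passed over all arrays in the fit of the report, and with an estimated correlation no list passed.

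Single arrays set against each other gave sizes without a test, since no stage had a replicate. From mature green to ripening, 7005 of 37227 probes were at least 4-fold apart in wild type, 2346 higher and 4659 lower, and 5496 of 36452 in ur, 2433 higher and 3063 lower. Between genotypes the number was 3059 at mature green, 3109 at breaker, 5481 at turning and 6327 at ripening. The flavonoid list had a median of -8.31 and the cell wall list of -7.30 in ur against wild type at ripening, each at percentile 0 of 10000 random lists matched on mean level. Random lists take no account of correlation between the genes of a list, estimated at 0.87 for flavonoids, so the percentiles are no test. The lycopene list stood at -0.33 at mature green, -0.66 at breaker, -1.53 at turning and -1.93 at ripening, at percentiles 6.47, 0.54, 0 and 0.05. The volatile list stood at -2.28 at turning and -2.22 at ripening, at percentiles 0.03 and 0.08. At mature green the cell wall list stood at 1.14 and ethylene response at 0.79, both at percentile 100.

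Chalcone synthases, which open flavonoid synthesis, rose and fell over the ur arrays. With 1 array per stage, an uneven array and a change between stages cannot be told apart. CHS1 stood at -2.96, 4.87, 4.17 and -2.13 in ur and between 4.22 and 6.15 in wild type. CHS2 stood at 1.38, 4.37, 3.70 and -4.46 in ur. MYB12, an activator of the pathway, was not well above background on the ur ripening array and was at least 229-fold lower there than in wild type. From mature green to ripening the cell wall list had a median of 1.52 in wild type and -3.35 in ur, and the pathogenesis-related list -3.85 and -2.55. The photosynthesis list had medians of -0.32 in wild type and 0.55 in ur. With median centring the wild type value was 0.01, and with spike-in scaling the ur value was -0.18. With normexp background correction the 6 counts of probes at least 4-fold apart were between 960 and 3029, and with spike-in scaling 80.2% of the ur ripening changes were lower in place of 55.7%.

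**Figure D4:**
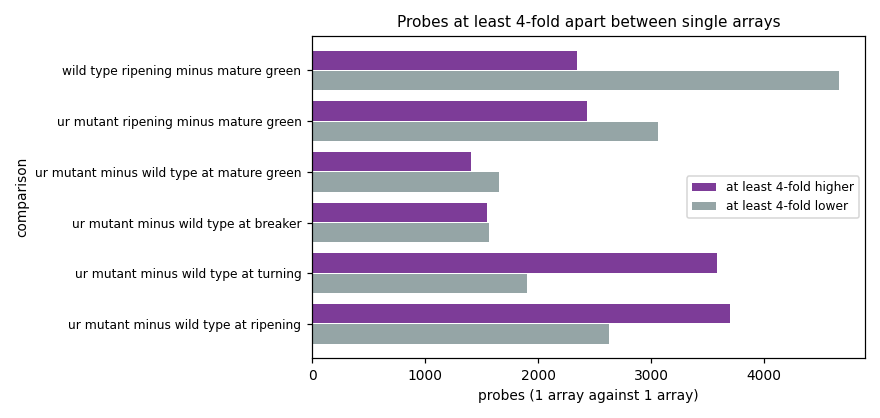
Number of probes at least 4-fold higher (purple) or lower (grey) in each comparison of 1 array with 1 array. The largest bar is wild type ripening against mature green, with 4659 lower probes.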

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

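The tests of the probes lost in ur and of the spike-in probes were chosen after their results were seen, while the splits of the arrays, the stage order and the slides were chosen before.

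Stage trends differed between the genotypes in 7 gene lists by a direct test of the difference. The camera adjusted p was 0.0117 for ethylene perception and response, 0.021 for carotenoid synthesis toward lycopene, 0.0115 for cell wall softening, 0.0115 for flavour volatiles, 0.000212 for photosynthesis, 0.021 for heat shock and 0.0082 for the cytosolic ribosome, and none passed with an estimated correlation. In limma 0 probes differed in slope, so all 35 splits of the arrays into 4 and 4 must give as many (2 at most), and the splits decide nothing here. Among the 23 other orders of the ur arrays the best, turning, mature green, ripening, breaker, had a correlation of 0.579 with the wild type slopes, 0.311 above the labelled order, which had 0.268, although the best of 23 is favoured by the choice. These are the 226 probes of the wild type trend. Over all probes that order had 0.532 and the labelled one 0.391, while its median ratio of ur to wild type slope was lower, 0.109 against 0.199. The order mature green, turning, breaker, ripening lay above the labelled one on all these measures, with 0.418, 0.516 and 0.208. An exchange of stages among the ur arrays and a course of ripening changed by the mutation could each give this, and both stay open, the genotype itself being untested without replicates.

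The mean level differed between ur and wild type at 3258 probes. Of the 35 splits, 1, the real one, gave as many, and the highest other gave 491. This sets the real split apart, but the splits did not keep the stages balanced. A slide effect alone could also give it. The 8 spike-in probes that responded on every array differed by at most 0.229 log2 units after scaling, under the smallest difference of 0.607 among the 3107 called probes in or above their range of brightness. This argues against labelling or scanning strength as the cause there. The background did differ between the slides, the 2 spike-in probes at background being up to 0.649 higher in ur after scaling. This is under the smallest difference of 1.47 among the 151 called probes dimmer than every responding spike-in, but 2 probes are few. In addition, 1 ERCC and 1 ETG control probe lay 3.97 and 4.09 higher in ur after scaling, above that difference. This pair also varied between arrays of the same slide, so it is no plain measure of the slide. The unscaled log2 signal of the ETG probe was 1.56, 1.38, 1.97 and 3.89 over the wild type stages. In ur it was 5.40, 6.75, 5.51 and 6.58. The control probes therefore do not settle whether a difference between the slides gave those calls. With 0 slides holding both genotypes, slide and genotype cannot be told apart, and an effect of either could be present.

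The probes of AF448522, DQ157795 and NM_001247908 were lower in ur by at least 9.6 log2 units in the mean, with dim signals raised to the background, while the 3 probes of NM_001247741 had a mean difference of -1.54. The gap of at least 8.06 log2 units argues against a lower level of the whole RIN transcript as the only cause. AF448522 and DQ157795 differ at 3 of 60 bases and by at most 0.285 log2 units on a wild type array, which argues against a few base differences under the probes. MC minus RIN varied by 0.211 log2 units over the ur arrays and by 9.03 over the wild type arrays, which is consistent with a RIN transcript joined to MC in ur, a hypothesis found from these same values. The MC probe has the same sequence as a probe of the RIN-MC entry, so its signal does not tell these entries apart. What the mutation changes in the DNA was not tested and stays open.

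Outside the gene probes, 1 ERCC control probe was 3.75 log2 units and 1 ETG control probe 3.86 log2 units brighter on the ur arrays than on the wild type arrays.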

How the results depend on the processing

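The slope difference stayed at 0 probes under every alternative run for it, which leaves out stage as a block. The wild type trend, 226 probes, was 94 with normexp (76.6% lower in place of 89.8%), 0 with quantile normalization, 134 with median centring, 0 from the value table, which counts gene names, 99 without a filter, 1 for early against late stages, 0 without a mean-variance trend and 46 for mature green against the 3 later stages (54.3% lower). Leaving arrays out gave 0 to 419: 0 without any wild type array, mutant mature green or mutant ripening, 73 without mutant breaker and 419 without mutant turning. The ur trend ranged from 0 to 77, with 77 without mutant turning. The mean difference, 3258, was 933 for early against late stages, 695 with stage as a block (58% lower in place of 44.7%), 1504 with spike-in scaling (57% lower) and 383 to 2902 with an array left out: 1463, 931, 732 and 967 without the wild type arrays in stage order, 383 without mutant mature green and 909 without mutant ripening.

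The counts of probes at least 4-fold apart, in the order wild type and ur ripening against mature green, then ur against wild type at the 4 stages, were 3029, 2083, 1069, 960, 2169 and 2482 with normexp, which came with an offset of 50. They were 3118, 2194, 896, 1008, 2193 and 3093 with the filter on all 8 arrays, where fewer probes are counted, and 15039, 12226, 8406, 9417, 12179 and 14171 with the 2-fold rule. The breaker count was 4810 with spike-in scaling. The share of lower probes moved from 66.5% to 54.6% in wild type with median centring and from 34.7% to 45% at turning with normexp. With spike-in scaling it moved from 55.7% to 80.2% in ur, and from 50.2% to 80.7% at breaker, 34.7% to 17.6% at turning and 41.5% to 54.2% at ripening. Array medians moved by -0.137 to 0.206 with median centring and by -0.565 to 0.451 with spike-in scaling.

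With an estimated correlation 0 lists passed in any contrast. For the wild type slope, 6 lists passed, 4 with normexp, median centring, no filter or the filter on all 8 arrays, 5 with quantile normalization or early against late stages, and 3 to 7 with an array left out (3 without wild type ripening). For the ur slope, 2 passed, 1 with the filter on all 8 arrays, 4 with spike-in scaling, 4 for mature green against later stages, and 2 to 6 with an array left out: 6 without mutant mature green, 4 without mutant turning and 5 without mutant ripening. For the slope difference, 7 passed, 4 with quantile normalization and 2 to 9 with an array left out (2 without wild type mature green, 4 without wild type ripening). For the mean difference, 6 passed, 3 with quantile normalization, 3 with the filter on all 8 arrays, and 4 to 6 with an array left out. Direction reversed for DXS1 from the value table (1.19), for photosynthesis without mutant mature green (ur slope 1.16e-05, slope difference 0.448), for its nuclear-encoded members alone (ur slope 1.12e-05) and for flavonoids without mutant ripening (ur slope 0.000801). The value for the nuclear-encoded members was adjusted without the chloroplast-encoded members as a list, so it differs from the one under other observations. With an array left out the camera adjusted p ranged from 9.4e-06 to 0.881 for the photosynthesis ur slope, from 2.9e-14 to 0.785 for its slope difference and from 0.000299 to 0.396 for the flavonoid ur slope.

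Of 1054 list results 864 stayed the same, 89 were weaker, 42 stronger and 55 moved, and of 7280 values of named genes 6648 stayed the same, 235 were weaker, 47 stronger and 349 moved. Of the 40 named values past the threshold, 32 kept it with normexp, 30 with quantile normalization, 40 with median centring, 28 from the value table and 12 for early against late stages. Of 588 list medians on single arrays 76 moved. Sign turned for 3 with normexp, 2 with quantile normalization, 6 with median centring, 6 from the value table, 3 without a filter, 11 with the filter on all 8 arrays and 18 with spike-in scaling. Where no reason is given, the cause was not tested. Spike-in scaling and mature green against later stages were chosen after the data were seen. Slide as a block was not run, because 0 slides hold both genotypes. The array numbers in the titles follow the stages in each genotype, so pairing by number is the fit with stage as a block. The median signal was 4.42 times the background on the ur breaker array, which limits what can be read of dim probes there.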

Other observations

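Genes of synthesis and signalling of jasmonate, a hormone of defence and wounding, were taken as a list after their values were seen, so no test is given for it. All 12 had slopes below 0 in wild type, with a median of -0.97 log2 units per stage. Their slope difference had a median of 0.86 and their mean difference one of 1.09, 11 of 12 being higher in ur. JAZ2 stood at 1.41, -0.01, -5.17 and -4.35 in wild type and at -0.46, -1.12, 1.47 and 0.94 in ur.

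Lipid transfer proteins, which carry lipids to the outer cell wall, were also taken as a list after their values were seen. All 5 had slopes below 0 in both genotypes, with a median of -2.40 in wild type and -3.01 in ur. In ur, LE16 and ltpg1 kept their level until turning, at 4.80 and 4.72, and stood at -4.99 and -4.81 at ripening. Subtilisin-like proteases, also chosen after their values were seen, had 5 of 6 slopes below 0 in wild type with a median of -1.28, and a median mean difference of 1.65.

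The 62 photosynthesis genes were split by genome after their values were seen. The 31 nuclear-encoded genes had a median slope of -1.13 in wild type (camera adjusted p = 5.45e-09, and adjusted p = 0.44 with an estimated correlation) and -0.47 in ur (camera adjusted p = 8.01e-06, and adjusted p = 0.606 with an estimated correlation). The 31 chloroplast-encoded genes had a median of 0.00 after rounding in wild type (camera adjusted p = 0.974) and 0.28 in ur, 30 of 31 being above 0 (camera adjusted p = 2.09e-06, and adjusted p = 0.63 with an estimated correlation).

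Of all probes, 192 were well above background on all wild type arrays and on no ur array, 6 of them lower by at least 8 log2 units even with the ur signals raised to the background, and 62 showed the reverse. Among the wild type arrays, the ur mature green array correlated best with mature green (0.935) and ur breaker with breaker (0.931). Among the same arrays, ur turning lay nearest to mature green (0.923) and ur ripening to breaker (0.89). Within ur, turning correlated with mature green at 0.953 and ripening with breaker at 0.932. The 23 other ERCC and ETG control probes had mean log2 signals of 1.37 to 1.43 in wild type and 1.73 to 1.9 in ur, and the bright pair stood at 4.37 to 6.75 on the ur arrays and 1.34 to 3.89 on the wild type arrays.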
